A study of Homo sapiens with 12 samples.

How the data were processed

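RNA sequencing libraries labelled A375 control, A375 COMMD4 knockout, SK-MEL-2 control and SK-MEL-2 COMMD4 knockout, 3 of each, were compared. The authors deposited a table of raw read counts per gene and a table of FPKM (fragments scaled by gene length and by mapped fragments), each with 20345 protein-coding genes and 1 column per sample, and every column was assigned to a group by its label. Per the file headers and values, the counts are whole numbers without normalization. The FPKM values were made by the authors with gene lengths that are not stated and that differ a little between samples. The aligner and the counting program are not given in the sources used here. The processing notes list the builds GRCm38 and hg38, while the coordinates in the files are those of GRCh37, since genes of chromosome 1 run to 249214145, past the end of that chromosome in hg38.

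Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 14354, and libraries were scaled by TMM factors. All 12 libraries entered a single quasi-likelihood fit with a mean for each of the 4 groups, which leaves 8 residual degrees of freedom. The contrasts were knockout over control in each line, their average, their difference (SK-MEL-2 minus A375) and SK-MEL-2 control over A375 control. All tests of genes are two-sided, p-values were adjusted by the method of Benjamini and Hochberg over all genes tested in a contrast, and a gene was called changed at an adjusted p under 0.05. The SE of a log2 fold change was taken as its size over the root of the F statistic. Displays and correlations used log2 CPM with a prior count of 2. The overlap of the lists of changed genes was tested by Fisher's exact test.

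The 27 gene lists were fixed before the data were examined, as were the contrasts, most of the other settings tried and the rule for naming genes. The GC correction and the few genes outside the rule were chosen after the values were seen. Lists with at least 5 tested members were tested by camera (limma 3.58.1) with a preset correlation of 0.01 between genes, with adjustment over the lists of a contrast, and again with a correlation estimated for each list. Members were counted by their own test over all genes and adjusted over the list alone. The rule names COMMD4, CDKN1A, CDK1, CCNB1, PIK3R1, PIK3R2 and AKT1 in every case. For each line it names the genes with the largest changes each way among those changed, with a mean log2 CPM of at least 2 and with no overlap between knockout and control libraries. The same conditions held for both lines together, with the smaller of the changes ranked. For the line difference and for the controls the largest each way were ranked. For each list up to 4 changed members with the largest changes qualify. The text may name fewer, from the top, and 1 gene that qualified is not reported here. Symbols are those of the file, where IL8, CTGF, CYR61 and GPR110 are CXCL8, CCN2, CCN1 and ADGRF1 in current naming. The file holds 13 symbols that a spreadsheet had turned into dates, replaced through their identifiers, and 103 symbols that occur for more than 1 identifier.

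Total counts ranged from 28906888 to 46330770 per library. The method was tested on simulated counts, with changes at known genes. All counts were drawn anew from the mean control level and the dispersion (spread) of each gene. They had no GC trend, no correlation between genes and the same dispersion in every group. Far fewer genes were called than in the real A375 comparison, 123 against 3542, which makes the adjusted threshold stricter on the simulated counts. Between the controls 114 were called, against 54, which makes it looser. The shares below hold for such counts and can differ in the real libraries. In A375, 16.7% of simulated 1.5-fold, 65.2% of 2-fold and 90.6% of 4-fold changes were called, and in SK-MEL-2 11.9%, 62.1% and 93.9%. For the average over the lines these shares were 42.4%, 80.0% and 97.0%, for the difference 2.99%, 18.2% and 89.1%, and for the controls 6.06%, 64.2% and 87.7%. Of the genes called there, 7.32%, 6.72%, 2.58%, 6.58% and 4.39% were unchanged genes, in the order A375, SK-MEL-2, average, difference and controls.

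Alternatives changed 1 choice at a time: RLE or upper quartile factors, DESeq2 1.42.0, limma-voom, no count filter or a CPM of at least 1 in 3 libraries, a block for the replicate number, log2 FPKM with a pseudocount of 1 or 0.1, a fit of the compared groups alone, a fold of at least 2, and leaving out each library in turn. For the lists they were an estimated correlation, a rotation test (fry), RLE factors, the CPM filter, the block and leaving out each library. A correction for GC content, as a lowess trend per library with a span of 0.2 over the 14086 tested genes (98.1%) with a known GC content, was added after seeing the data, alone and with the block. No column was left out. No pair of libraries of a group held copies of each other.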

Results

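RNA was sequenced in 12 libraries that the labels assign to A375 and SK-MEL-2, established human melanoma cell lines, each as a control and as a COMMD4 knockout, with 3 libraries in each of the 4 groups. COMMD4 belongs to the COMMD family, whose members form complexes that take part in endosomal sorting. The series title places COMMD4 in cutaneous melanoma and in signalling through p85, PI3K and Akt, so the comparisons asked which genes differed between the libraries labelled knockout and control in each line, and whether the lines differed in this. Total counts ranged from 28906888 to 46330770 per library, 14354 of 20345 protein-coding genes had enough counts to be tested, and the spread between libraries of a group was 19.6% (biological coefficient of variation). Levels below are CPM (counts scaled to library size) with the SD over n = 3 libraries, and changes are log2 fold changes with their SE. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure a spread between libraries that can be technical alone. The preparation text in the labels describes sorted cells and droplet single-cell libraries, whereas the files hold 1 column of gene counts per sample.

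COMMD4 itself (ENSG00000140365, GRCh37 chromosome 15, 75628232 to 75634268) was counted in every library. The counts were 1331, 1257 and 1435 in the libraries labelled A375 control and 1932, 1543 and 1438 in those labelled A375 knockout. They were 1641, 1352 and 1618 in the SK-MEL-2 controls and 1781, 1506 and 1290 in the SK-MEL-2 knockouts. The level was 42.2 ± 3.96 CPM in A375 controls and 44.6 ± 7.61 CPM in A375 knockouts, a log2 change of 0.08 (SE 0.15, adjusted p = 0.725). In SK-MEL-2 it was 51.5 ± 4.29 CPM in controls and 37.8 ± 5.10 CPM in knockouts, a log2 change of -0.45 (SE 0.15, adjusted p = 0.165), lower in 3 of 3 knockout libraries. The log2 changes of the lines differed by -0.52 (SE 0.21, adjusted p = 0.148). No loss of COMMD4 mRNA was detectable in A375, where the sign of the change turned to -0.19 after a correction for GC content. A count over the whole gene does not register a small edit of the coding sequence, and the edited position is not given in the sources used here.

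**Figure D1:**
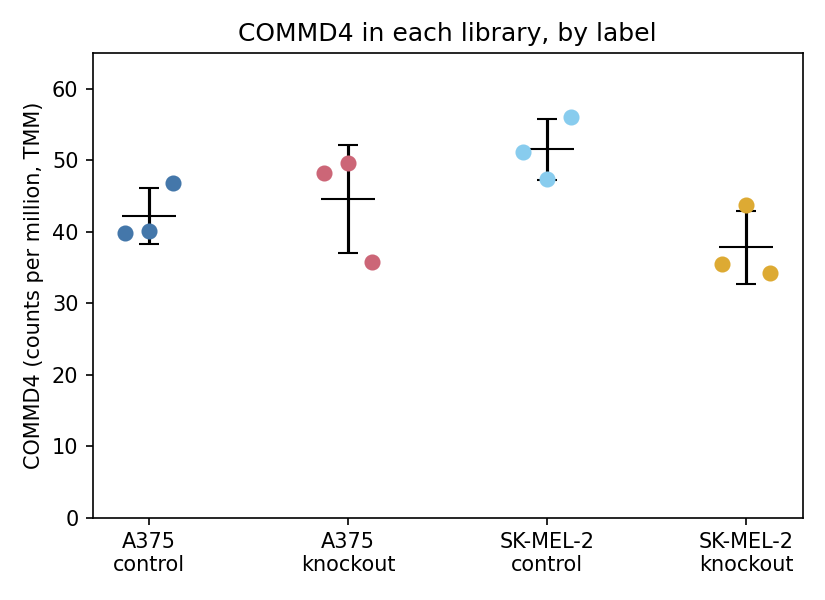
COMMD4 level in CPM (vertical axis) in each of the 12 libraries (points) of the 4 labelled groups, with the mean and SD of each group. The A375 knockout libraries, with a mean of 44.6, overlap the A375 controls, and the 3 SK-MEL-2 knockout libraries, with a mean of 37.8, lie below the SK-MEL-2 controls.

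Across the tested genes, the libraries labelled A375 control and SK-MEL-2 control had Pearson correlations of 0.963 to 0.983 in log CPM, close to the 0.985 to 0.988 among A375 controls and the 0.980 to 0.986 among SK-MEL-2 controls. The A375 knockouts stood apart, with correlations of 0.926 to 0.949 to the A375 controls, against 0.979 to 0.985 among themselves. The SK-MEL-2 knockouts had correlations of 0.952 to 0.980 to their controls and 0.959 to 0.987 among themselves. The first principal component held 42.8% of the variance. Its scores ran from -38.0 to -22.7 in the 6 controls, from -1.88 to 4.07 in the SK-MEL-2 knockouts and from 58.9 to 70.1 in the A375 knockouts. The second component held 20.6% and spread libraries within each group. It also set the control labels apart, with scores of 7.06 to 34.2 in A375 controls and -43.5 to -3.45 in SK-MEL-2 controls. The Spearman correlation across genes between GC content and a library's level relative to the mean ran from -0.61 in SK-MEL-2 knockout replicate 1 to 0.67 in SK-MEL-2 knockout replicate 2. The scores of these libraries on the second component were 41.7 and -40.5.

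**Figure D2:**
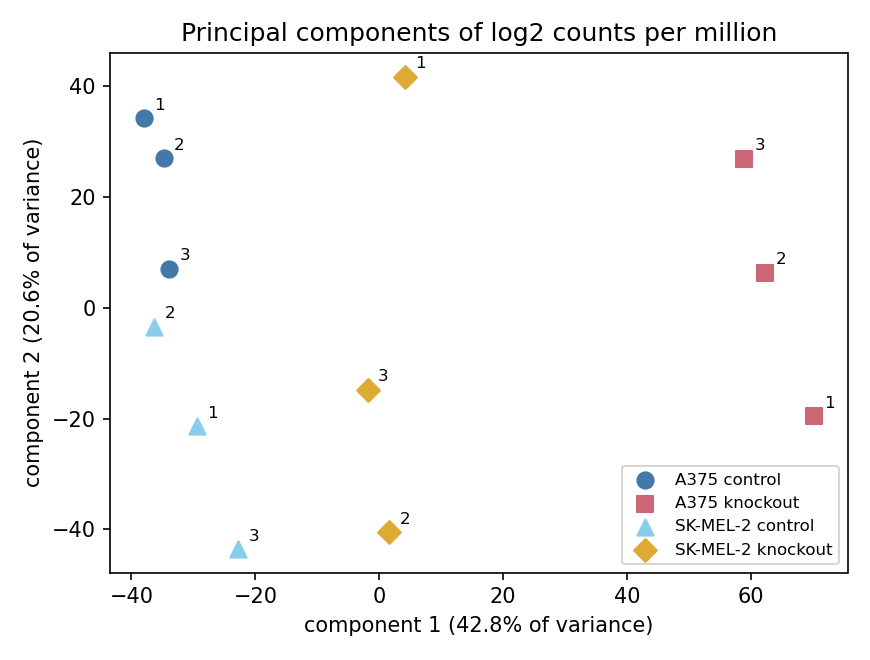
Scores of the 12 libraries on the first (42.8% of the variance) and second (20.6%) principal components of log CPM, with colours for the 4 labelled groups. The controls of both labelled lines share the low end of the first axis, the SK-MEL-2 knockouts lie near 0 and the A375 knockouts lie between 58.9 and 70.1.

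The comparison of the control libraries asked how the controls of the labelled lines differ. LCN2, which encodes the secreted lipocalin 2, was higher in SK-MEL-2 controls, at 39.9 ± 7.32 CPM against 15.9 ± 3.08 CPM in A375 controls (log2 1.32, SE 0.20, adjusted p = 0.0152). CDC20, an activator of the anaphase-promoting complex, was also higher, at 420 ± 88.3 against 199 ± 23.0 CPM (log2 1.08, SE 0.19, adjusted p = 0.0397). SPP1, which encodes osteopontin, was lower, at 2.18 ± 0.907 against 13.1 ± 1.23 CPM (log2 -2.58, SE 0.33, adjusted p = 0.00899). In all, 54 genes differed, 20 higher and 34 lower in SK-MEL-2, and 29 of them differed at least 2-fold. No gene was above 5 CPM in every control library of a line and below 0.5 CPM in every control library of the other. The count of 54 is unstable. It was 3709 in a fit of the 6 control libraries alone, 974 with DESeq2, 846 after GC correction and 104 or 82 with FPKM. Leaving out a library gave 3, 9 or 11 without A375 control replicate 1, 2 or 3, 28 or 29 without A375 knockout replicate 2 or 3, and 0, 16 or 17 without SK-MEL-2 control replicate 1, 2 or 3. It gave 1695, 97 or 27 without SK-MEL-2 knockout replicate 1, 2 or 3. At an unadjusted p under 0.05, 3567 genes differed.

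In A375, the libraries labelled knockout had much higher levels of a set of genes that were low in the controls. The cancer-testis antigen MAGEA1 rose from 0.675 ± 0.197 to 21.7 ± 4.57 CPM (log2 4.99, SE 0.32, adjusted p = 9.4e-07). SNAI2, a transcription factor of neural crest and mesenchymal cells, rose from 0.663 ± 0.283 to 15.3 ± 3.36 CPM (log2 4.53, SE 0.36). TFAP2B, a transcription factor of the neural crest, rose from 24.8 ± 2.01 to 472 ± 57.9 CPM, a 19.0-fold change. SOD3, ABCA8 and ENPP2, the last encoding the secreted enzyme autotaxin, rose by log2 4.29, 4.22 and 4.11. Among the genes named here, the largest fall was that of the tetraspanin-like gene TM4SF18, from 25.1 ± 3.51 to 0.0748 ± 0.0659 CPM (log2 -8.22, SE 0.51, adjusted p = 6.25e-07). The adhesion receptor gene GPR110, the secreted proteoglycan gene ESM1, the sphingosine-phosphate receptor gene S1PR1 and SERPINB7 had log2 changes of -6.07, -5.92, -5.48 and -5.34. The growth factor gene PDGFB and the integrin gene ITGB4, whose position overlaps GALK1, each had a log2 change of -5.19. Every one of these genes separated the 3 knockout from the 3 control libraries without overlap, a condition of the rule by which they were named.

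In all, 3542 of 14354 genes (24.7%) changed in A375 by the edgeR quasi-likelihood test, 1863 higher and 1679 lower in the knockout, and 1603 changed at least 2-fold. After GC correction 2312 were higher and 2432 lower. The count was 2154 without A375 control replicate 1, 2237 without A375 control replicate 2 and 2254 without A375 knockout replicate 1. On chromosome 14, where AKT1 and FOS lie, the tested genes had a median log2 change 0.31 above that of all genes after GC correction.

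Among the gene lists tested by camera, the targets of YAP and TEAD, the transcriptional output of the Hippo pathway, fell with the lowest p in A375. Of 20 tested members 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median log2 change of -1.29 (camera, adjusted p = 3.71e-18, and adjusted p = 0.0286 with an estimated correlation). ANKRD1 changed by log2 -4.63 (SE 0.29), CTGF by -3.40 (SE 0.29), CYR61 by -3.18 (SE 0.41) and CRIM1 by -2.48 (SE 0.18). Genes of undifferentiated melanoma cells also fell, 9 of 20, with 1 higher (10 and 1 adjusted over the list alone, median -0.54, adjusted p = 2.15e-08, and adjusted p = 0.0343 with an estimated correlation). In this list the Wnt antagonist gene DKK1 changed from 104 ± 10.7 to 3.48 ± 0.369 CPM (log2 -4.90, SE 0.16) and the neurotrophin receptor gene NGFR by log2 -2.18 (SE 0.19).

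A further 6 lists passed the preset test in A375 and not the test with an estimated correlation. Splits that mixed A375 knockout and control libraries also passed 4 to 10 lists by the preset test, with 0 genes called. Immediate early and heat shock genes were higher, 10 of 18 with 0 lower (12 adjusted over the list alone, median 0.69, adjusted p = 0.0028, and adjusted p = 0.399 with an estimated correlation). Among them were EGR2 (log2 2.29, SE 0.39), EGR1 (1.60, SE 0.24) and FOS (1.58, SE 0.23). Genes of MHC class I presentation were higher, 6 of 16 with 0 lower (7 adjusted over the list alone, median 0.34, adjusted p = 0.0346, and adjusted p = 0.638 with an estimated correlation), with HLA-B at log2 1.53 (SE 0.19) and HLA-C at 1.23 (SE 0.18). Of 20 MAPK output genes 7 were lower and 2 higher (8 and 2 adjusted over the list alone, median -0.24, adjusted p = 0.0174, and adjusted p = 0.399 with an estimated correlation), led by FOSL1 (-2.47), EPHA2 (-2.33), EPHA4 (-1.90) and CCND1, the cyclin D1 gene (-1.85, from 852 ± 27.1 to 236 ± 49.8 CPM). Of 28 matrix and adhesion genes 12 were lower and 5 higher, the same counts as adjusted over the list alone, with L1CAM at log2 -2.89 (median -0.33, adjusted p = 0.0174, and adjusted p = 0.211 with an estimated correlation). Of 23 genes of the amino acid response and unfolded protein response 9 were lower and 1 higher (9 and 2 adjusted over the list alone), with the amino acid transporter gene SLC7A5 at -2.20 (median -0.18, adjusted p = 0.0174, and adjusted p = 0.399 with an estimated correlation). Of 40 genes of G2 and mitosis 5 were lower and 0 higher (4 and 0 adjusted over the list alone), among them KIF11 (-1.21, SE 0.24), ANLN (-1.13, SE 0.22) and CENPF (-1.02, SE 0.27). The median of this list was -0.26 (adjusted p = 0.0174, and adjusted p = 0.712 with an estimated correlation), and its adjusted p was 0.0824 by a rotation test and 0.161 without A375 knockout replicate 1. That library's omission also gave adjusted p = 0.0944 for the MAPK and MHC class I lists. Without A375 knockout replicate 3 the adjusted p was 0.148 for the amino acid list and 0.0614 for the matrix list, and without SK-MEL-2 control replicate 3 it was 0.0544 for MHC class I. After GC correction all 6 still passed the preset test. The medians then were 0.40 for immediate early and heat shock genes (9 higher and 1 lower), 0.20 for MHC class I (7 and 1), -0.30 for the amino acid list (2 and 10) and -0.13 for G2 and mitosis (0 and 10).

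The other lists did not pass in A375 as a whole, though members changed in several. For NF-kB targets, 6 of 22 were higher and 5 lower (7 and 5 adjusted over the list alone), with the interleukin 1 genes IL1B at log2 -4.94 and IL1A at -3.71 and the cytokine gene CSF2 at -3.66. The median of this list was 0.21, while its mean of -0.37 and the direction of the test were negative (adjusted p = 0.816). For PI3K and Akt components, 4 of 32 were higher and 1 lower, the same counts as adjusted over the list alone (median 0.06, adjusted p = 0.691). After GC correction 9 of this list were higher and 5 lower (median 0.021, adjusted p = 0.566). The insulin receptor substrate gene IRS1 fell from 24.9 ± 1.12 to 6.93 ± 0.565 CPM (log2 -1.85, SE 0.14, adjusted p = 2.6e-06), and FOXO1 and the regulatory subunit gene PIK3R3 rose by log2 1.41 (SE 0.18) and 1.40 (SE 0.16). FOXO targets had 6 higher and 1 lower of 22, by both adjustments, with TXNIP at 1.82 and SOD2 at 1.76 (adjusted p = 0.0715). Pigmentation genes had 3 higher and 3 lower of 16 (4 and 3 adjusted over the list alone, adjusted p = 0.467), with DCT at log2 4.11, still only 1.13 ± 0.339 CPM, and MLPH at -2.98. The melanocyte genes TYR and MLANA had too few counts to be tested. Mesenchymal markers had 6 higher and 6 lower of 29 (8 and 7 adjusted over the list alone, adjusted p = 0.38), with SNAI2 at log2 4.53 and the matrix metalloproteinase gene MMP9 at -4.44. The COMMD and retriever list, without COMMD4, had 3 lower of 15, namely COMMD8 (-0.82), VPS29 (-0.60) and COMMD3 (-0.52), and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.385). After GC correction COMMD8 was at -0.40 (adjusted p = 0.0258), while VPS29 (-0.20, adjusted p = 0.21) and COMMD3 (-0.20, adjusted p = 0.215) no longer passed. Interferon-stimulated genes had 7 higher and 1 lower of 27 (8 and 1 adjusted over the list alone, adjusted p = 0.263), S phase genes 2 lower of 33 (1 adjusted over the list alone, adjusted p = 0.0806) and hypoxia genes 5 lower of 25 (5 adjusted over the list alone, adjusted p = 0.203). After GC correction the S phase list, with 6 lower, and the FOXO targets, with 7 higher and 1 lower, passed the preset test (adjusted p = 0.0485 each) and not the test with an estimated correlation (0.744 and 0.632). Apoptosis regulators had 3 higher and 5 lower of 24 (4 and 5 adjusted over the list alone, adjusted p = 0.409). Cholesterol synthesis had 2 higher and 2 lower of 21 by both adjustments (adjusted p = 0.583). Copper handling had 1 higher and 1 lower of 15 (0 and 1 adjusted over the list alone, adjusted p = 0.553). p53 targets had 1 higher of 25 (0 adjusted over the list alone, adjusted p = 0.836) and epithelial markers 1 lower of 12 (1 adjusted over the list alone, adjusted p = 0.38). After GC correction 2 p53 targets were higher and 3 lower, and 2 epithelial markers were lower.

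In SK-MEL-2, TFAP2B again rose, from 23.8 ± 1.30 to 158 ± 44.7 CPM (log2 2.73, SE 0.18, adjusted p = 1.92e-05, 6.64-fold). VAT1L, the integrin gene ITGA9 and ENPP2 rose by log2 2.69 (SE 0.31), 2.59 (SE 0.28) and 2.58 (SE 0.22). OLFML3 rose from 2.01 ± 1.16 to 10.3 ± 1.71 CPM, and the protease inhibitor gene A2M and the neural adhesion gene CNTN1 rose by log2 2.17 and 2.13. MMP9 fell from 10.6 ± 6.12 to 0.363 ± 0.212 CPM (log2 -4.91, SE 0.51, adjusted p = 0.000443). LCN2 fell from 39.9 ± 7.32 to 1.43 ± 0.298 CPM (log2 -4.81, SE 0.24, adjusted p = 1.11e-06), TMPRSS15 by log2 -4.41, CSF2 by -4.02, IL1A by -3.14 and ZP4 by -3.03. The chemokine gene IL8 fell from 684 ± 217 to 102 ± 21.5 CPM (log2 -2.75, SE 0.24), ESM1 changed by log2 -2.55 and the transcription factor gene PRDM1 by -2.42.

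In all, 425 of 14354 genes (2.96%) changed in SK-MEL-2, 244 higher and 181 lower, and 256 changed at least 2-fold. The count was 839 with DESeq2, 1029 after GC correction (502 higher and 527 lower) and 73 in a fit of the 6 SK-MEL-2 libraries alone. It was 168 or 186 without SK-MEL-2 control replicate 1 or 2 and 244 without SK-MEL-2 knockout replicate 3.

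NF-kB targets fell as a group in SK-MEL-2. Of 22 members 11 fell and 0 rose (18 and 0 adjusted over the list alone), with a median log2 change of -0.93 (camera, adjusted p = 1.42e-36, and adjusted p = 0.0432 with an estimated correlation). Besides CSF2, IL1A and IL8, with log2 changes of -4.02, -3.14 and -2.75, the chemokine gene CCL2 changed by log2 -2.32 (SE 0.30). The p with an estimated correlation was 0.128 after GC correction and 0.0674 without SK-MEL-2 knockout replicate 1. Matrix and adhesion genes were also lower, 2 of 28 with 0 higher (6 adjusted over the list alone, median -0.24, adjusted p = 0.000148, and adjusted p = 0.0432 with an estimated correlation), namely COL6A3 (-1.26, SE 0.27) and NCAM1 (-0.59, SE 0.10). For this list the p with an estimated correlation was 0.131 after GC correction and 0.245 without SK-MEL-2 knockout replicate 1. After GC correction 8 matrix genes were lower.

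A further 7 lists passed the preset test in SK-MEL-2, all downward, and not the test with an estimated correlation. Splits that mixed SK-MEL-2 knockout and control libraries also passed 4 to 9 lists by the preset test. Of 40 genes of G2 and mitosis 3 fell and 0 rose, namely KIF2C (-0.62, SE 0.14), PTTG1 (-0.57, SE 0.13) and CDCA8 (-0.48, SE 0.11), and 17 fell adjusted over the list alone (median -0.39, adjusted p = 3.81e-14, and adjusted p = 0.289 with an estimated correlation). Of 20 genes of undifferentiated melanoma 2 fell, INHBA (-1.39) and SOX9 (-1.26), and 8 adjusted over the list alone (median -0.26, adjusted p = 6.51e-05, and adjusted p = 0.114 with an estimated correlation). In the list of MHC class I presentation 0 of 16 members passed (1 lower adjusted over the list alone, median -0.35, adjusted p = 0.000187, and adjusted p = 0.447 with an estimated correlation). Apoptosis regulators had 2 lower of 24, BIRC3 (-2.13) and BCL2A1 (-1.39), and 3 adjusted over the list alone (median -0.01, adjusted p = 0.0365, and adjusted p = 0.135 with an estimated correlation). Mesenchymal markers had 4 lower and 1 higher of 29 (7 and 1 adjusted over the list alone), with MMP9 at -4.91 and SNAI2 at 2.46 (median -0.10, adjusted p = 0.038, and adjusted p = 0.569 with an estimated correlation). Hypoxia genes and genes of the amino acid response had 0 members passing by either adjustment, with medians of -0.24 and -0.13 (adjusted p = 0.0173 and 0.0365, and adjusted p = 0.703 and 0.507 with an estimated correlation). Without SK-MEL-2 knockout replicate 1 the adjusted p was 0.455 for the mesenchymal list, 0.0725 for the amino acid list and 0.0705 for apoptosis regulators, and the hypoxia list changed direction (0.511). The medians were then -0.14 for undifferentiated melanoma and -0.22 for MHC class I, and both lists still passed the preset test (adjusted p = 0.000933 and 0.0453). The mesenchymal p was 0.0776 or 0.059 without SK-MEL-2 control replicate 1 or 3, 0.051 without A375 knockout replicate 2 and 0.0837 without SK-MEL-2 knockout replicate 3. The amino acid p was 0.0771 or 0.0958 without SK-MEL-2 control or knockout replicate 3, and the apoptosis p was 0.0554 or 0.0625 without SK-MEL-2 knockout replicate 2 or 3. By a rotation test the mesenchymal (adjusted p = 0.257), MHC class I (0.13), hypoxia (0.474) and amino acid (0.158) lists did not pass. After GC correction these 7 lists still passed the preset test, with more members called. Lower were 20 genes of G2 and mitosis, 7 of undifferentiated melanoma (1 higher), 3 of MHC class I, 4 apoptosis regulators, 9 mesenchymal markers (4 higher, median -0.028), 1 hypoxia gene and 2 of the amino acid response.

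The lists that did not pass in SK-MEL-2 held few changed members. YAP and TEAD targets had 1 higher of 20, ANKRD1 (log2 0.96, SE 0.23, adjusted p = 0.0486), and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.102). After GC correction ANKRD1 no longer passed (0.94, adjusted p = 0.06) and 3 members of this list were lower. PI3K and Akt components had 1 lower of 32, the catalytic subunit gene PIK3CD (-0.72, SE 0.18, adjusted p = 0.0479), and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.209). FOXO targets had 1 lower of 22, SOD2 (-0.97), with 1 higher and 2 lower adjusted over the list alone (adjusted p = 0.596). After GC correction 2 PI3K and Akt components were higher and 1 lower, and 1 FOXO target was higher and 1 lower. MAPK output genes had 1 higher and 2 lower of 20 (2 and 3 adjusted over the list alone, adjusted p = 0.659), pigmentation genes 3 lower of 16, BCL2A1 (-1.39) among them (2 higher and 3 lower adjusted over the list alone, adjusted p = 0.834), and copper handling 1 lower of 15 by both adjustments (adjusted p = 0.596). In the lists of COMMD and retriever (adjusted p = 0.596), S phase (0.0524, and 0.021 after GC correction), interferon-stimulated genes (0.834), cholesterol synthesis (0.596) and heat shock and immediate early genes (0.894), 0 members passed by either adjustment. With an estimated correlation the S phase list did not pass before or after GC correction (adjusted p = 0.703 and 0.776). Without SK-MEL-2 knockout replicate 1 it passed the preset test (median -0.24, adjusted p = 4.64e-05) and not the test with an estimated correlation (0.589). p53 targets (adjusted p = 0.834) and epithelial markers (0.333) had 0 passing, and 2 and 1 lower adjusted over the list alone. After GC correction 3 p53 targets and 1 each of the epithelial, S phase and cholesterol lists were lower, and 1 heat shock or immediate early gene was higher. Median, mean and test differed in sign in SK-MEL-2 for FOXO targets (0.04, -0.04, down), pigmentation (0.06, 0.13, down), interferon-stimulated genes (0.06, 0.03, down), copper handling (0.09, -0.02, down) and heat shock (-0.08, 0.05, down).

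The genes fixed in advance for the cell cycle and for PI3K did not pass in either line in the edgeR fit of all 12 libraries without GC correction. The cyclin-dependent kinase inhibitor gene CDKN1A changed by log2 -0.04 (SE 0.22, adjusted p = 0.921) in A375 and by -0.04 (SE 0.22, adjusted p = 0.966) in SK-MEL-2. CDK1 changed by -0.53 (SE 0.25, adjusted p = 0.136) and -0.45 (SE 0.25, adjusted p = 0.464), and the cyclin B1 gene CCNB1 by -0.19 (SE 0.16, adjusted p = 0.395) and -0.57 (SE 0.16, adjusted p = 0.0831). PIK3R1, which encodes p85 alpha, changed by 0.23 (SE 0.32, adjusted p = 0.613) and 0.71 (SE 0.32, adjusted p = 0.353). PIK3R2, which encodes p85 beta and has a second overlapping identifier in the file, changed by 0.49 (SE 0.20, adjusted p = 0.0942) and -0.09 (SE 0.20, adjusted p = 0.896). AKT1 changed by 0.53 (SE 0.18, adjusted p = 0.0525) in A375, where the genes of its chromosome, 14, were raised as a whole, and by -0.07 (SE 0.18, adjusted p = 0.92) in SK-MEL-2. After GC correction CDK1 (-0.54, adjusted p = 0.00415) and CCNB1 (-0.61, adjusted p = 0.0497) passed in SK-MEL-2, and PIK3R1 (0.58, adjusted p = 0.0153) and AKT1 (0.25, adjusted p = 0.0154) passed in A375. In A375 CDK1 was then at -0.11, CCNB1 at -0.050, PIK3R2 at 0.18 and CDKN1A at -0.30, none of them past the threshold. These are mRNA levels, and the files hold no measure of protein or of phosphorylation.

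The genes changed in A375 and in SK-MEL-2 overlapped. Whether the labels stand for different lines stays open, so this overlap need not be agreement between lines. TFAP2B, VAT1L, ITGA9, ENPP2, A2M and CNTN1 rose in both lines, with log2 changes in A375 of 4.25, 2.84, 2.92, 4.11, 3.26 and 2.90. CSF2, IL1A, ESM1, PRDM1, TMPRSS15, GPR110 and SERPINB7 fell in both, with log2 changes in SK-MEL-2 of -4.02, -3.14, -2.55, -2.42, -4.41, -2.15 and -2.09. Of the 244 genes higher in SK-MEL-2, 193 were also higher in A375, against 31.7 for independent lists (odds ratio 28.2, Fisher's exact test, two-sided, p = 1.97e-125). Of the 181 lower, 116 were also lower in A375, against 21.2 (odds ratio 14.4, Fisher's exact test, p = 1.54e-63). Together 309 genes changed the same way in both lines and 19 in opposite ways, and 372 of the 425 SK-MEL-2 genes (87.5%) had the same sign in A375. Over all tested genes the fold changes of the lines had a Spearman correlation of 0.17 and a Pearson correlation of 0.37, and genes are not independent replicates, so the Fisher p-values are only a guide. The count of 309 was 533 with DESeq2 and 641 after GC correction, and 134, 137 or 193 without SK-MEL-2 control replicate 1, SK-MEL-2 control replicate 2 or SK-MEL-2 knockout replicate 3.

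On average over both lines 2634 genes changed, 1348 higher and 1286 lower, and 951 changed at least 2-fold. Genes of G2 and mitosis had 15 lower of 40 with 0 higher (27 adjusted over the list alone, median -0.35, adjusted p = 5.67e-07, and adjusted p = 0.412 with an estimated correlation). YAP and TEAD targets had 14 lower and 1 higher of 20, by both adjustments (median -0.84, adjusted p = 2.46e-14, and adjusted p = 0.0215 with an estimated correlation). Genes of undifferentiated melanoma had 9 lower and 1 higher of 20, by both adjustments (median -0.36, adjusted p = 4.39e-10, and adjusted p = 0.0215 with an estimated correlation). Matrix genes had 10 lower and 3 higher of 28 (13 and 4 adjusted over the list alone, median -0.27, adjusted p = 0.000547, and adjusted p = 0.047 with an estimated correlation). The total was 4185 after GC correction and 4078 without SK-MEL-2 knockout replicate 1.

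**Figure D3:**
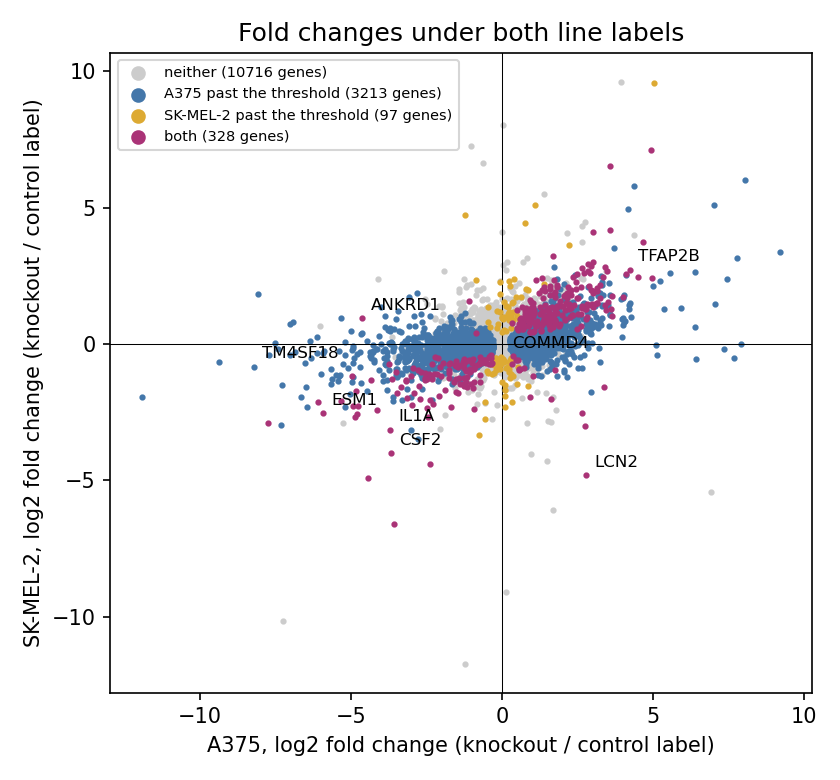
Log2 fold change of each tested gene in SK-MEL-2 (vertical axis) against that in A375 (horizontal axis), each as knockout over control, with colours for the genes changed in 1 or both lines. Of 328 genes changed in both lines 309 lie in the quadrants of equal sign, while LCN2 and ZP4 rose in A375 and fell in SK-MEL-2.

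The last comparison asked whether the knockout and control libraries differed by different amounts in the lines, as SK-MEL-2 minus A375. LCN2 rose in A375, from 15.9 to 110 CPM, and fell in SK-MEL-2, from 39.9 to 1.43 CPM, a difference of log2 -7.60 (SE 0.31, adjusted p = 1.33e-07). ZP4 and FDCSP went the same opposite ways, with differences of -5.79 (SE 0.33) and -4.98 (SE 0.28), as did the complement gene C3, whose position overlaps GPR108, with -3.66 (SE 0.69). TM4SF18 fell in A375 and changed by -0.84 (adjusted p = 0.234) in SK-MEL-2, a difference of 7.39 (SE 0.61, adjusted p = 3.87e-05). ANKRD1 fell in A375 and rose in SK-MEL-2 (adjusted p = 0.0486, and 0.06 after GC correction), a difference of 5.58 (SE 0.37, adjusted p = 7.27e-06). PDGFB, SPANXC, MARCHF4, ITGB4, DKK1 and S1PR1 fell in A375 alone by the test, with differences of 5.27, 5.14, 4.91, 4.77, 4.39 and 4.35. After GC correction DKK1 (-0.54, adjusted p = 0.0274) and S1PR1 (-1.15, adjusted p = 0.0283) fell in SK-MEL-2 as well. SK-MEL-2 knockout replicate 1 stood below the other SK-MEL-2 knockouts for several of these genes. ITGB4 was at 21.2 CPM in it against 155 and 141 CPM in replicates 2 and 3, PDGFB at 0.937 against 6.90 and 5.58, and SPANXC at 0.778 against 7.28 and 8.29. For these 3 genes that library moved in the direction of the A375 knockouts. SPANXC belongs to a multicopy family, so its reads are uncertain. In all, 1071 genes differed between the lines in this way, 590 with a more positive and 481 with a more negative change in SK-MEL-2.

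By list, YAP and TEAD targets had 11 of 20 more positive in SK-MEL-2 with 0 more negative (15 and 0 adjusted over the list alone, median difference 1.22, adjusted p = 7.19e-17, and adjusted p = 0.0405 with an estimated correlation). NF-kB targets had 11 of 22 more negative with 0 more positive (15 and 2 adjusted over the list alone, median -1.35, adjusted p = 9.3e-11, and adjusted p = 0.321 with an estimated correlation). MHC class I genes had 4 of 16 more negative (9 adjusted over the list alone, median -0.79, adjusted p = 6.54e-06, and adjusted p = 0.369 with an estimated correlation). HLA-B differed by log2 -1.88 (SE 0.27). G2 and mitosis had 0 of 40 members differing by either adjustment (median -0.07, adjusted p = 0.291). After GC correction 6 of them were more negative (median -0.30, adjusted p = 0.00567, and adjusted p = 0.787 with an estimated correlation), and the MHC class I median was -0.52, with 8 members more negative. IRS1 differed by 2.00 (SE 0.19, adjusted p = 0.000126). The count of 1071 was 1928 with DESeq2, 2076 after GC correction and 1881 without SK-MEL-2 knockout replicate 2. It was 530 or 548 without A375 control replicate 1 or 2, 628 or 675 without A375 knockout replicate 1 or 2, 567 or 630 without SK-MEL-2 control replicate 1 or 3, and 601 without SK-MEL-2 knockout replicate 3.

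**Figure D4:**
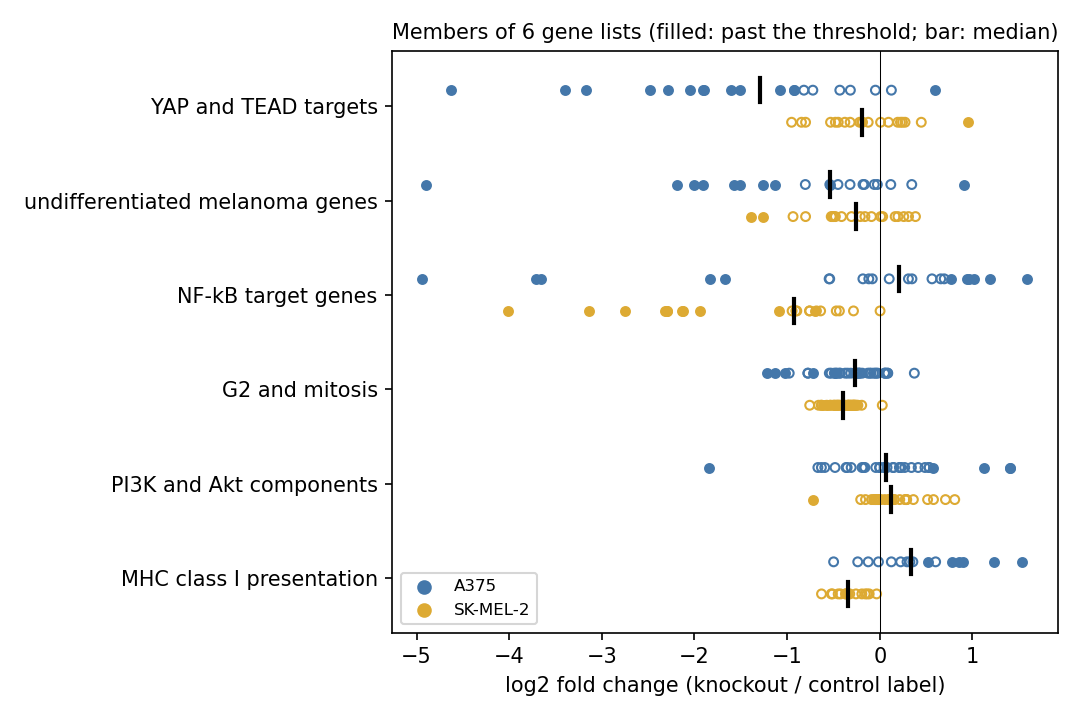
Log2 fold change of the members of selected gene lists, knockout over control, in A375 and SK-MEL-2, where each point is a gene, filled points passed the test for that gene and bars are list medians. The YAP and TEAD targets have a median of -1.29 in A375, and the NF-kB targets have a median of -0.93 in SK-MEL-2.

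Lists of markers of other cell types were also compared. Of 11 leukocyte markers 3 were tested and of 10 erythroid markers 1, too few for a list test, with 1 leukocyte marker lower in A375 and 0 changed in SK-MEL-2, and 0 erythroid markers changed in either line. Of 10 endothelial markers 4 were tested, of which 3 were lower and 1 higher in A375 and 2 lower in SK-MEL-2. The receptor gene TIE1 changed by log2 -2.08 in A375 and -1.90 in SK-MEL-2, and ROBO4 by -0.71 (adjusted p = 0.0471) in SK-MEL-2. Keratinocyte markers had 2 of 5 lower in A375 (3 adjusted over the list alone, adjusted p = 0.134), KRT15 (-2.27) and KRT14 (-2.09), with 1 higher and 3 lower after GC correction, and 0 in SK-MEL-2 by either adjustment (adjusted p = 0.596). Fibroblast markers had 1 higher and 1 lower of 9 in A375 by both adjustments (adjusted p = 0.911) and 0 in SK-MEL-2, with 1 higher adjusted over the list alone (adjusted p = 0.138).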

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

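The tests of on and off genes, of lines with alike expression and of a mixture were chosen only after the result was seen, as were the GC correction and the genes CXCL1, CXCL2, CXCL3, NFKBIA, XDH, MME and IL1RL1.

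The change between knockout and control libraries differed between the lines, by the test of the difference itself, for 1071 genes. Values are SK-MEL-2 minus A375 in log2 units. Among genes that rose in A375, MAGEA1 differed by -2.59, SNAI2 by -2.06, SOD3 by -3.28, TFAP2B by -1.52, ABCA8 by -2.78, ENPP2 by -1.53, LCN2 by -7.60, ZP4 by -5.79, FDCSP by -4.98 and C3 by -3.66. HLA-B differed by -1.88, HLA-C by -1.39, FOXO1 by -0.89, PIK3R3 by -0.82, SOD2 by -2.73, TXNIP by -2.99 and NCAM1 by -1.06. Among genes that fell in A375, TM4SF18 differed by 7.39, GPR110 by 3.93, ESM1 by 3.38, S1PR1 by 4.35, SERPINB7 by 3.25, PDGFB by 5.27, ITGB4 by 4.77, PRDM1 by 1.73, ANKRD1 by 5.58, SPANXC by 5.14, MARCHF4 by 4.91, SPP1 by 2.98, XDH by 3.80, MME by 3.71 and IL1RL1 by 2.75. CTGF differed by 2.86, CYR61 by 2.22, CRIM1 by 2.29, DKK1 by 4.39, NGFR by 2.57, FOSL1 by 1.94, EPHA2 by 1.81, EPHA4 by 1.45, CCND1 by 1.37, SLC7A5 by 2.01, L1CAM by 2.19, IRS1 by 2.00, MLPH by 3.15, KRT14 by 2.68 and TMPRSS15, which fell further in SK-MEL-2, by -2.04. Among genes that passed in SK-MEL-2 alone, OLFML3, which after GC correction also passed in A375 (-1.01, adjusted p = 0.0187), differed by 3.22, IL8 by -2.20, BIRC3 by -1.59, BCL2A1 by -1.39, CXCL1 by -2.40, CXCL3 by -2.47 and NFKBIA by -1.39. CXCL2, which passed in both lines in opposite ways, differed by -2.88.

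By list, the median difference was 1.22 for YAP and TEAD targets (adjusted p = 0.0405 with an estimated correlation). It was -1.35 for NF-kB targets, -0.79 for MHC class I presentation, -0.63 for heat shock and immediate early genes and 0.28 for undifferentiated melanoma genes (adjusted p = 0.321, 0.369, 0.321 and 0.208 with an estimated correlation). It was -0.38 for mesenchymal markers, -0.20 for FOXO targets and 0.23 for MAPK output genes (adjusted p = 0.604, 0.423 and 0.423 with an estimated correlation). These 7 lists passed the preset test alone. After GC correction the median was -0.34 for heat shock and immediate early genes, -0.52 for MHC class I presentation and -0.24 for mesenchymal markers. G2 and mitosis then also passed the preset test (-0.30, adjusted p = 0.00567) and not the test with an estimated correlation (0.787).

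Other splits of the libraries bear on these counts. For the 1071 genes with a line difference 3 of 100 splits gave as many, the real split included. This share cannot exclude chance, since the counts depended on which libraries were moved. Drawn splits that mixed the knockouts of the labels mostly gave 0 to 2 genes, but the highest of them gave 5339 and 2294. Those that kept the knockout labels gave 269 to 785. They hold the whole difference between the knockouts of the labels (1359 genes), so they cannot serve as counts by chance. The split with 785 kept every group and only exchanged which controls go with which knockouts. The split with 5339, several times the real count, exchanged replicates 2 and 3 of the A375 knockout with those of the SK-MEL-2 knockout. It kept the controls. Its 2 groups of knockouts had correlations with GC content of 0.50, 0.67 and 0.31 against 0.21, -0.24 and -0.61. For the 309 changed the same way 1 of 100 splits gave as many. The next count, 19, came from a split that kept every group and only turned the A375 labels around. It thus counts the genes changed in opposite ways. The highest count of a split that mixed libraries was 4. This share rests on A375 as well, since every drawn split that moved A375 libraries gave 0 such genes. The drawn splits that kept the A375 groups and mixed the SK-MEL-2 groups gave 0 to 4, and they are too few for a share under 0.05. The part of chance in the SK-MEL-2 groups is therefore left open here too. For the 2634 genes changed on average 3 of 100 splits gave as many, but this share rests on A375, since every drawn split that moved A375 libraries gave 0 or 1 genes. The drawn splits that kept the A375 labels gave 834 to 5087, so for this count the part of chance in the SK-MEL-2 groups is left open. The highest, 5087, exchanged SK-MEL-2 knockout replicate 1 with SK-MEL-2 control replicate 3. Its SK-MEL-2 groups had correlations with GC content of 0.30, -0.19 and -0.61 against 0.44, 0.67 and 0.31. The splits with 5339 and 5087 thus set libraries of unlike GC trend against each other. No split was run after GC correction, so the part of GC content in these counts was not tested. The 10 splits of 3 against 3 libraries are too few for a share under 0.05. In them the real and the highest other counts were 3542 and 0 for genes in A375 (1 split as high), 425 and 12 in SK-MEL-2 (1 split), 54 and 1 between the controls (1 split), 8 and 10 for lists in A375 (4 splits) and 9 and 9 for lists in SK-MEL-2 (3 splits). The other splits passed 4 to 10 lists in A375, where they called 0 genes, and 4 to 9 in SK-MEL-2. The number of lists past the preset test therefore does not set the real groups apart from mixed ones.

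The control libraries of the 2 labelled lines resemble each other, with correlations of 0.963 to 0.983. A single cell line behind both labels predicts no genes that are on in all controls of a label and off in all controls of the other, and 0 such genes were found, which is consistent with it. The count of genes that differ cannot decide, since it ran from 0 to 3709 over the settings tried. Of the genes differing in the controls, 24.1% (13 of 54) differed the same way in the knockouts. For 2 lines with alike expression this lies above the bound against and below the bound for. The latter also asked for more genes at least 2-fold apart in the controls than the 29 found, so it could not be met. A fit of the controls alone gave 240 such genes. Between the knockouts of the labels 0 genes were on in a label and off in the other, against 15 between the A375 groups. Of 11224 genes with log2 CPM of at least 2, 95 differed 2-fold at any p between controls, against 842 between the A375 groups. The on and off genes and the few 2-fold differences between controls argue against 2 lines of clearly distinct expression behind the labels. They do not tell 1 line from 2 lines with alike expression. The knockouts of the labels differ in 1359 genes, and which libraries the labels describe stays open.

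The libraries differ in their trend with GC content, and the log2 changes had a Spearman correlation with GC content across genes of 0.43 in A375, -0.18 in SK-MEL-2, 0.28 on average, -0.48 for the line difference and 0.55 between the controls. GC bias as the whole cause of the calls is argued against by a correction for it, after which 89.1% of the genes called in A375 and 97.6% of those called in SK-MEL-2 were still called the same way. The shares were 95.0% on average, 91.3% for the line difference and 90.7% between the controls. The median size of the log2 change of the called genes was 0.93 before and 0.81 after in A375. GC content could still account for some of the A375 calls that ended.

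The SK-MEL-2 knockouts lie between the controls and the A375 knockouts on the first principal component. A mixture of control cells with cells of the A375 knockout allows few SK-MEL-2 calls opposite in direction to the A375 knockout, and 2.35% (10 of 425) were, under the bound of 5%. A stricter test, added after the first was seen, argues against a mixture as the whole cause, since 12.5% of the calls (53 of 425) lie beyond both the SK-MEL-2 controls and the A375 knockouts, LCN2 and ZP4 among them. A mixture as a part of the cause stays open. A weaker effect of the same knockout, which the labels would give, may account for the genes in between and was not tested.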

How the results depend on the processing

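The GC correction, alone and with the block, was chosen only after the result was seen, as were the genes MME and CXCL1; the other alternatives were planned.

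Of 117 called results for named genes, under 2794 alternatives, 2600 kept direction and call, 194 lost the call and 0 reversed. Most of these genes were named for the largest changes among called genes, many with no overlap between knockout and control libraries. The alternatives reuse the same libraries, so this stability was likely by selection and says little about the other calls. Results for named genes that had not been called are outside this tally. Some of them gained a call, such as 3 with DESeq2, 5 after GC correction and 3 without SK-MEL-2 knockout replicate 1. The called lists of YAP and TEAD targets in A375 and of NF-kB targets in SK-MEL-2 passed under every alternative of 1 choice run for them. With an estimated correlation the NF-kB list did not pass after GC correction (adjusted p = 0.128) or without SK-MEL-2 knockout replicate 1 (0.0674). The cause of the changes below was not tested, except where a smaller number of libraries or a fold limit leaves fewer genes by construction. Genes changed in A375 (3542) numbered 1603 with a fold of at least 2, those in SK-MEL-2 (425) 256, on average (2634) 951, the same way in both lines (309) 183, and between controls (54) 29. With DESeq2 there were 839 in SK-MEL-2, 1928 for the line difference (1071), 533 the same way and 974 between controls. After GC correction there were 1029, 4185 on average, 2076, 641 and 846, and 98 between controls with the block added. FPKM gave 104 and 82 between controls with pseudocounts of 1 and 0.1, and the latter shifted the median of all genes by 0.14 in the line difference and by -0.11 between controls. More genes were lower than higher in A375 (46.6% to 49.5% higher, against 52.6%) with FPKM, after GC correction without or with the block, and without A375 control replicate 1 or 2, A375 knockout replicate 1 or SK-MEL-2 knockout replicate 1. In SK-MEL-2 this held after GC correction without the block (48.8%, against 57.4%). A fit of the 2 groups alone gave 73 in SK-MEL-2 and 3709 between controls. The common dispersion (the spread of counts within groups) was 0.0186 in that fit of the controls, against 0.0385 in the fit of all 12 libraries. The smaller spread goes with the larger count between controls.

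Libraries that share a replicate number are not more alike within a line (correlations of -0.25, -0.10 and -0.35 in A375 and -0.01, -0.38 and 0.20 in SK-MEL-2), so the block pairs unrelated libraries. With it the counts were 1980 in A375, 107 in SK-MEL-2 (72.0% higher, against 57.4%), 1606 on average, 308 for the difference, 82 the same way and 0 between controls. At an unadjusted p under 0.05 edgeR without the block gave 3567 there.

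Leaving out 1 library gave 2154 to 5137 genes in A375, 168 to 459 in SK-MEL-2, 2015 to 4078 on average, 530 to 1881 for the difference, 134 to 303 the same way and 0 to 1695 between controls. It gave 5 to 10 lists in A375 (8) and 7 to 10 in SK-MEL-2 (9). The counts of 5137 and 1695 came without SK-MEL-2 knockout replicate 1, which is in neither comparison and enters through the shared fit. With an estimated correlation 2 lists passed in A375 and 2 in SK-MEL-2, and by the rotation test 14 in A375 and 6 in SK-MEL-2. For G2 and mitosis in A375 the adjusted p of 0.0174 became 0.712 with an estimated correlation, 0.0824 by rotation and 0.00187 to 0.161 with 1 library left out, and in SK-MEL-2 it was 0.289 with an estimated correlation.

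COMMD4 in A375 (0.08) reversed to -0.13 with FPKM and either pseudocount, to -0.19 after GC correction without or with the block, and ran from -0.017 to 0.21 with 1 library left out. In SK-MEL-2 (-0.45) it ran from -0.58 to -0.37. The other genes that reversed had values near 0 that had not passed. AKT1 in SK-MEL-2 was 0.098 and 0.10 with FPKM and ran from -0.24 to 0.11 with 1 library left out. PIK3R2 in SK-MEL-2 ran from -0.29 to 0.12, CDKN1A from -0.31 to 0.22 in SK-MEL-2 and from -0.14 to 0.051 in A375. CXCL1 in A375 (0.10) was -0.0034 and -0.0036 with FPKM and ran from -0.096 to 0.19. MME in SK-MEL-2 (0.06) was -0.36 with limma-voom, -0.20 with the block, -0.055 with FPKM and a pseudocount of 0.1, -0.21 with GC correction and block, and -0.42 to 0.52 with 1 library left out. For the hypoxia list in SK-MEL-2, which had passed (adjusted p = 0.0173), the adjusted p ran from 9.95e-05 to 0.511, where the list reversed, without SK-MEL-2 knockout replicate 1.

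In simulated data 16.7% of 1.5-fold changes in A375 and 2.99% of 1.5-fold line differences were called. Only 123 and 76 genes were called there, against 3542 and 1071 in the real libraries. The adjusted threshold was therefore stricter in the simulation, and these shares can be too low for the real comparisons.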

Other observations

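The genes named in the first and second paragraphs were chosen after their values were seen; the tests by chromosome and around COMMD4 were planned before theirs.

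In A375, 15 genes were above 5 CPM in every control library and below 0.5 CPM in every knockout library, and 0 showed the opposite. The xanthine oxidoreductase gene XDH changed by log2 -4.97 (SE 0.34), the interleukin 33 receptor gene IL1RL1 by -4.46 (SE 0.56) and the membrane peptidase gene MME, known as CD10, by -3.66 (SE 0.54). In the SK-MEL-2 knockouts the same genes were at 2.66 ± 0.829, 3.64 ± 1.76 and 3.45 ± 2.31 CPM (SD, n = 3), and 0 genes in SK-MEL-2 met both limits. SPANXC and related genes of a multicopy family are among the 15, with reads that are uncertain.

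In SK-MEL-2, several chemokine genes of the same cluster fell. CXCL1 fell from 241 ± 73.8 to 49.0 ± 15.5 CPM (log2 -2.30, SE 0.26, adjusted p = 0.000727), CXCL2 by log2 -1.94 (SE 0.26, adjusted p = 0.00184) and CXCL3 by -2.13 (SE 0.30, adjusted p = 0.00243). NFKBIA, which encodes an inhibitor of NF-kB that is itself a target, changed by log2 -1.08 (SE 0.26, adjusted p = 0.0445). In A375 the changes were 0.10 (adjusted p = 0.787) for CXCL1, 0.94 (SE 0.25, adjusted p = 0.0157) for CXCL2, 0.35 (adjusted p = 0.381) for CXCL3 and 0.31 (adjusted p = 0.392) for NFKBIA.

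A gain of chromosome 14 in the A375 knockout cells was tested as a hypothesis. After GC correction the 469 tested genes of chromosome 14 had a median log2 change 0.31 above that of all genes, with 73.6% of them on that side. The uncorrected fit called 151 higher and 26 lower on it. The next largest medians were -0.12 on chromosome 1 and 0.12 on chromosome 19. In SK-MEL-2 the largest median, also on chromosome 14, was 0.058, which argues against a change of a whole chromosome in most cells there. By library, relative to the A375 controls, the chromosome 14 median was 0.056, 0.035 and 0.027 in the SK-MEL-2 knockouts. In the SK-MEL-2 controls it was -0.0017, -0.023 and -0.030, so a change in a part of the cells stays open. A copy number change in the A375 knockout cells may therefore account for part of the calls on chromosome 14, though no DNA was measured.

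Loss of a segment around COMMD4 was tested as a hypothesis for the knockouts. The 88 tested genes within 5 Mb had a median log2 change of 0.013 in A375 and -0.040 in SK-MEL-2, both above the bound for a loss. This argues against a loss over most of that window. A loss of COMMD4 with a few neighbours would hardly move the median of 88 genes, so it was not tested.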
